A study of Homo sapiens with 57 samples.

How the data were processed

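Messenger RNA was sequenced from HCT116 cells, a human colorectal carcinoma line, in 9 libraries that form 3 groups of 3. Per the labels, the cells carried an Spt5-HA-dhfr fusion, and were grown without trimethoprim, the ligand that stabilises a dhfr degron. Per the labels, an Avi-tagged Spt5 fragment of residues 1 to 820 was induced with doxycycline at 2 ug/ml for 24 hours. The groups differ in the form of the CTR1 region of that fragment, named WT, TA7 or TE7 in the labels. RNA was extracted with Trizol and selected with oligo-dT, and 1 ug entered library preparation with a Tecan/Nugen kit, per the labels' protocols. The series has 57 samples, of which 48 with other measurements (nascent transcript sequencing and chromatin immunoprecipitation) are not analysed here.

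Adapters were handled with cutadapt 2.3 and transcripts quantified with Salmon 1.3.0, per the submitters' processing notes, which also name the hg19 genome build. The transcript set, the library type and the bias options are not given in the sources used here. Per the file headers, each deposited table gives for every transcript its length, its effective length, its TPM and an estimated count of reads. The estimated counts deposited by the authors are not normalized and divide reads shared by several transcripts among them, so only 12.7% to 13.8% of the estimates above 0 are whole to within 0.001. The TPM values deposited by the authors are scaled per effective length and to the same total in each library. Effective length is the number of positions in a transcript that could give a read, as estimated for each library. Transcripts of one gene share sequence, so estimates for single transcripts can be uncertain even at high depth, and shared reads can move between similar transcripts from library to library.

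The tables list 228715 transcripts by identifier, without gene names. The gene tables used here held 0 rows with a transcript identifier of these tables, so no transcript was assigned to a gene. The tests therefore ran on transcripts, as the design written before the data were examined provides. The level of the Spt5 gene, the gene list tests, the index of long minus short genes and the share of reads in retained-intron transcripts need gene names or annotation and are not analysed here. The planned rule for naming genes took those with adjusted p under 0.05, a mean of at least 5 CPM, groups that did not overlap, and the largest fitted changes. It was applied to TE7 vs WT without its criteria on gene symbol and coding status, and stopped at 2 transcripts that were higher and 2 that were lower.

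Estimated counts were rounded to whole numbers. Library totals ranged from 64364751 to 90805283 estimated reads. Transcripts with low counts were removed with the default filter of edgeR 4.0.16 on the group factor, which left 78478 transcripts that hold 99.67% to 99.79% of the reads. Libraries were scaled with TMM factors, which ranged from 0.92 to 1.037. One quasi-likelihood model of edgeR (glmQLFit and glmQLFTest) with group as its only term was fitted to the 9 libraries. Its contrasts were TA7 minus WT, TE7 minus WT and TE7 minus TA7, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are in CPM, the usual unit of counts relative to library size, computed here with the TMM factors. A fold against a group at 0 reads in every library is a lower bound, computed against 3 reads per library, and covers counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Reads were not matched to molecules, so read counts are not counts of independent molecules.

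Shares of reads by transcript length were compared with exact two-sided permutation tests of 3 against 3 libraries, for which the smallest possible p is 0.1. The length classes, with limits at 500, 1000, 2000, 4000 and 8000 bases, were chosen after the data were examined. Similarity of the comparisons with WT was set beside 20 simulated data sets with no difference between groups, of which 5 were fitted in full, and beside 5 simulated with TA7 equal to WT and TE7 as measured. The second kind of simulation was also chosen after the data were examined.

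The test was tried on simulated counts for 72511 transcripts with about 200 of them changed in TE7. For TE7 vs WT it recovered 12% of changes of 2-fold and 60% of changes of 4-fold among transcripts of at least 5 CPM, and 0% of either size between 1 and 5 CPM, with 1 false call. For TE7 vs TA7 it recovered 18% and 60% at 5 CPM or more, and 0% below, with 2 false calls. For TA7 vs WT, in which nothing was changed, it made 0 calls. Low recovery with so few changed transcripts means that single transcripts of low abundance could change without a call.

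Alternatives listed before the data were examined were DESeq2 1.42.0, other scalings and filters, fits of only the groups compared, a replicate block, an effective length offset, limma 3.58.1 on log2 TPM with 1 or 0.1 added, a test against a 1.5-fold change and the omission of each library. Computation used R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1.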

Results

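The libraries held 64364751 to 67628672 estimated reads in WT, 65723341 to 90805283 in TA7 and 68578355 to 73794335 in TE7. Between 87229 and 99993 transcripts had reads in each library, and 83503 of the 228715 listed were at 0 in all 9. Spearman correlations over 61735 transcripts were 0.84 to 0.876 within WT, 0.87 to 0.883 within TA7 and 0.886 to 0.892 within TE7. Between TE7 and WT libraries they were 0.783 to 0.839, below every value within a group. Between TA7 and WT they were 0.846 to 0.879, inside the range found within groups. On the first axis of a multidimensional scaling of log2 CPM, with 19.1% of the variance, the TE7 libraries lay at 3.34, 3.26 and 2.33. WT replicate 1 (0.45) and TA7 replicate 1 (0.59) lay closer to TE7 than the other libraries of their groups, which lay between -1.67 and -3.27. WT replicate 1 also stood alone on the second axis, at 5.29 against 0.7 or less elsewhere.

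Spt5 is an elongation factor that travels with RNA polymerase II, and CTR1 is a region of it. The first comparison asks whether steady-state mRNA differs between cells induced to express the TE7 and the WT form. Of 78478 transcripts tested, 7378 differed, with 3603 higher and 3775 lower in TE7 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). A change of at least 2-fold was found for 3334 of them, 1492 higher and 1842 lower, and the median absolute log2 change of the called transcripts was 0.92. Calls were concentrated among abundant transcripts. Of 1587 transcripts at 100 CPM or more, 31.06% differed, and of 38622 below 1 CPM, 2.16% differed. Simulated changes of 4-fold were recovered in 60% at 5 CPM or more and in 0% between 1 and 5 CPM. The concentration may therefore reflect what the test can detect. The 3 TE7 libraries lay all above or all below the 3 WT libraries for 32.9% of transcripts, where chance gives 10%. That 10% is an average over groupings, and a single grouping can lie well above it where shifts are shared across a library. The balance of directions was not stable: with library size alone 4092 were higher and 3608 lower, and without WT replicate 1 5363 and 4539. Without WT replicate 2 or 3 the count was 3485 or 3610, and without TE7 replicate 1, 2 or 3 it was 3408, 3129 or 3515. Other processing choices gave between 1003, for a test against a 1.5-fold change, and 15850, for DESeq2.

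Long transcripts were more often lower in TE7. Of 1770 transcripts of 8000 bases or more, 404 were lower and 54 higher in TE7 than in WT. Among 9902 of 4000 to 7999 bases, 1293 were lower and 429 higher. Shorter transcripts went the other way, with 1060 higher and 489 lower among 17165 of 1000 to 1999 bases. Among those of at least 5 CPM, the median log2 change was -0.43 at 8000 bases or more and 0.2 at 1000 to 1999 bases. Under RLE scaling the median at 8000 bases or more was -0.43, and with library size alone it was -0.44.

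**Figure D1:**
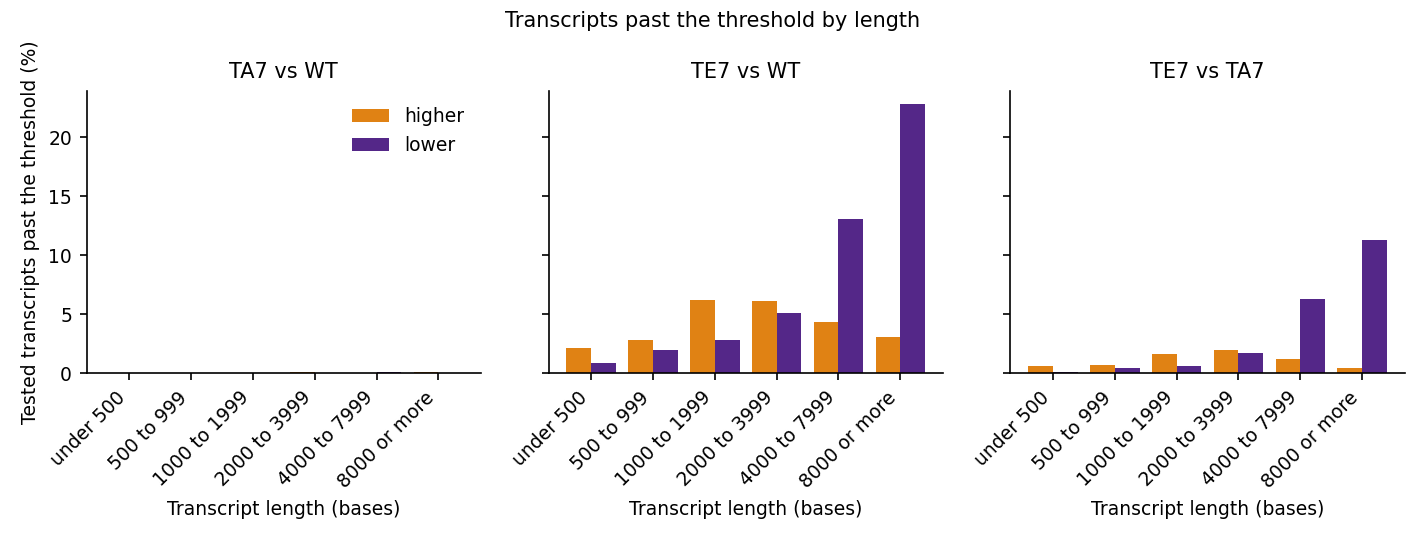
Bars give the percentage of tested transcripts that passed the threshold, higher (orange) or lower (purple) in the group named first, by transcript length in bases, for each of the 3 comparisons. In TE7 vs WT, 22.82% of transcripts of 8000 bases or more were lower and 3.05% higher, while the bars of TA7 vs WT are too low to see, at 0.11% or less. Length classes are not matched on abundance, so bar heights do not compare directly between them. At least 5 CPM was reached by 1070 of 1770 transcripts of 8000 bases or more, and by 2367 of 25092 of 500 to 999 bases.

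Reads from transcripts of 4000 bases or more made up 19.62% ± 0.55 of the total in TE7, 22.78% ± 2.21 in WT and 23.4% ± 0.92 in TA7 (SD, n = 3). Each TE7 library, at 18.99% to 19.94%, lay below each library of the other groups. WT replicate 1, at 20.41%, was the nearest. With a limit of 3000 bases this separation from WT was lost, since TE7 replicate 1 was at 32.22% and WT replicate 1 at 32.16%, with exact permutation p = 0.2 for TE7 vs WT (n = 3). The TE7 minus WT difference of -3.16 percentage points and the TE7 minus TA7 difference of -3.78 both had exact permutation p = 0.1 (two-sided). That is the smallest this test allows for 3 against 3 libraries, so neither can pass 0.05 in it. TA7 and WT differed by 0.62 points, less than the spread within WT, with exact permutation p = 0.8. In a family of 18 such tests, of 6 length classes in 3 comparisons, the smallest Benjamini-Hochberg adjusted p was 0.2. In it, transcripts of 1000 to 1999 bases held 28.87% ± 0.43 of reads in TE7 and 27.34% ± 1.34 in WT (SD, n = 3). These groups overlapped, with exact permutation p = 0.3, so the higher calls among shorter transcripts had no separate share of reads beside them. TA7, at 26.79% ± 0.63, did not overlap with TE7, with exact permutation p = 0.1. The TE7 libraries also had longer fragments, at an estimated 167.33 ± 0.58 bases against 160.0 ± 4.58 in WT and 157.33 ± 8.02 in TA7 (SD, n = 3).

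**Figure D2:**
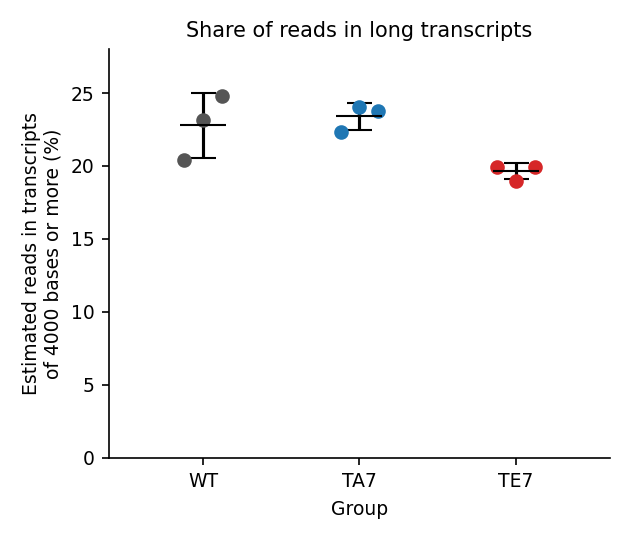
Points give the percentage of estimated reads from transcripts of 4000 bases or more in each library, by group, and black marks the group mean with its SD (n = 3). The 3 TE7 libraries lie between 18.99% and 19.94%, below the lowest WT library at 20.41%.

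The 4 transcripts with the largest fitted changes under the naming rule were at 0 reads in every library of one group, and the tables pair none of them with a gene. ENST00000630065.2_1, of 2994 bases, was at 31.7 ± 7.77 CPM in TE7 (SD, n = 3) and at 0 reads in all WT and TA7 libraries. It was at least 684-fold higher in TE7 than in WT and at least 792-fold higher than in TA7, with edgeR adjusted p of 0.00196 and 0.00659. The latter was 0.0619 in the edgeR fit with a replicate block. ENST00000650154.1_2, of 4458 bases, was at 30.5 ± 16.7 CPM in TE7 and 0 reads in WT, at least 657-fold higher. Its edgeR adjusted p was 0.0101, and 0.0525 with a replicate block. Its mean in TA7 was 17.8 ± 14 CPM, with 203 to 2055 reads per library, at least 384-fold higher than in WT. This transcript still did not pass in edgeR for TA7 vs WT (adjusted p = 0.129) or for TE7 vs TA7 (0.722). In DESeq2 its difference between TA7 and WT did pass, with adjusted p = 3.47e-15, and over all alternatives the adjusted p ranged from that to 0.466.

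ENST00000424123.7_4, of 8295 bases, was at 31.7 ± 20 CPM in WT and 32.3 ± 13.8 in TA7 (SD, n = 3), and at 0 reads in all TE7 libraries. It was at least 739-fold lower in TE7 than in WT and at least 754-fold lower than in TA7, with edgeR adjusted p of 0.00359 and 0.0104. ENST00000591446.6_2, of 3243 bases, was at 30.7 ± 14.8 CPM in WT and 23.6 ± 12.8 in TA7, and at 0 reads in TE7. It was at least 717-fold lower than in WT and at least 551-fold lower than in TA7, with edgeR adjusted p of 0.0028 and 0.00907. Transcripts that share sequence can exchange reads in the authors' quantification, so a value of 0 for one transcript does not show that its gene was silent.

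**Figure D3:**
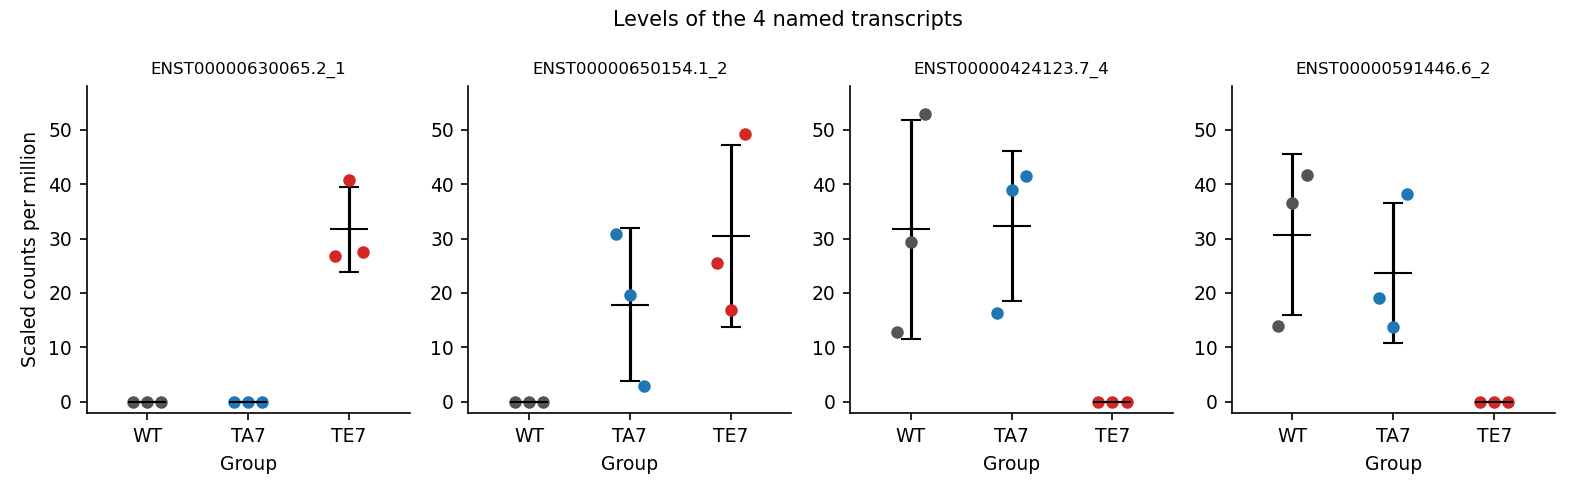
Points give the scaled CPM of the 4 named transcripts in each library, by group, on a linear axis, and black marks the group mean with its SD (n = 3). The first pair is at 0 in WT and reaches 49.1 CPM in TE7, and the second pair is at 0 in TE7 and reaches 52.8 CPM in WT.

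The second comparison set TA7 against WT. It called 48 transcripts, 32 higher and 16 lower in TA7 (edgeR quasi-likelihood test, n = 3 per group), of which 33 differed by at least 2-fold. At an unadjusted p under 0.05 there were 6065, where chance gives 3924. Groups did not overlap for 14.1% of transcripts, where chance gives 10%. Both chance values are averages over groupings. Where shifts are shared across a library, a single grouping can lie well above them, so the excess alone does not show an effect of TA7. At 4000 bases or more 8 were higher and 7 lower, too few to compare with shorter transcripts, and the median log2 change of those of at least 5 CPM was 0.01. The count was 159 without WT replicate 1, 76 without WT replicate 2, 25 without TA7 replicate 2, and 5, 7 or 6 without TE7 replicate 1, 2 or 3, which enter the same fit and the same filter on low counts. The balance turned to 14 higher and 20 lower without TA7 replicate 1. The count was 0 in edgeR when only the TA7 and WT libraries were fitted, with 4523 of 71232 tested at an unadjusted p under 0.05. The chance value of 3924 is for 78478 tested and does not apply to that fit. It was also 0 in edgeR with a replicate block, with 5556 at an unadjusted p under 0.05. It was 2206 in DESeq2 and 116 in limma on log2(TPM + 1).

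The third comparison set TE7 against TA7, and is also the test of whether their differences from WT differ. It called 2411 transcripts, 1011 higher and 1400 lower in TE7 (edgeR quasi-likelihood test, n = 3 per group). The excess of lower calls turned in a fit of only these groups, with 2499 higher and 2174 lower, and was absent without WT replicate 1, with 2395 and 2387. A change of at least 2-fold was found for 827. At 8000 bases or more 200 were lower and 8 higher, and at 4000 to 7999 bases 627 were lower and 120 higher. Of the 7378 transcripts called in TE7 vs WT, 2234 were also called here, and 173 transcripts were called here alone. The count was 4782 without WT replicate 1, 1300 without WT replicate 2, 1269, 362 or 298 without TA7 replicate 1, 2 or 3, and 651, 380 or 617 without TE7 replicate 1, 2 or 3. Other processing choices gave between 121, for a test against a 1.5-fold change, and 10555, for DESeq2.

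Of the 48 transcripts called in TA7 vs WT, 44 were called in the same direction in TE7 vs WT, 32 higher and 12 lower, and 0 in opposite directions. The shared count was 151 without WT replicate 1, 67 without WT replicate 2, 17, 15 or 22 without TA7 replicate 1, 2 or 3, and 5, 7 or 5 without TE7 replicate 1, 2 or 3. It was 0 in edgeR fits of only the groups compared, where TA7 vs WT had 0 calls and 4523 of 71232 tested transcripts at an unadjusted p under 0.05. It was also 0 in edgeR with a replicate block, and was 1729 in DESeq2 and 111 in limma on log2(TPM + 1). Independent lists of the main sizes would share 1.47 higher and 0.77 lower. The lists are not independent, since both comparisons use the same fit and its estimate of the spread of each transcript. Of the 48, 35 were also called in TE7 vs TA7, where 3.07% of all tested transcripts were called. Simulated unchanged groups shared 0, but almost nothing is called in such data, so that value sets no chance level for the overlap. Over all tested transcripts the log2 changes correlated at 0.512, against 0.502 in simulation, and their covariance was 0.716 against 0.432. That simulation had no difference between TE7 and WT, while the measured TE7 had 7378 calls. Neither simulated value is therefore a matched reference for TA7 equal to WT. Transcripts are not independent replicates, and both comparisons used the same 3 WT libraries, which are too few to split, so part of the excess may come from the shared controls. Among the transcripts called in TE7 vs WT, 89.64% lay on the same side of WT in TA7, with a median ratio of the TA7 to the TE7 change of 0.29. In 5 simulations with TA7 equal to WT these values averaged 62.86% and 0.07. TA7 replicate 1 lay towards TE7, and without it, for the same calls, they were 83.61% and 0.26, against 61.51% and 0.07 in simulation. Without WT replicate 3 the percentage was 81.66%, the lowest with 1 library left out. Both kinds of simulation drew each transcript independently, without shifts shared across a library. The measured libraries had such shifts, as the positions of WT replicate 1 and TA7 replicate 1 show. The simulated values therefore set no chance level for TA7 equal to WT. A shift shared by the WT libraries could also put TA7 and TE7 on the same side.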

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

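The share of reads from long transcripts and the fits that remove a length trend or leave out WT replicate 1 and TA7 replicate 1 together were chosen after the result was seen. Between TE7 and TA7, 2411 transcripts passed the threshold, which tests whether their differences from WT differ. Of the 10 splits of these 6 libraries, 1 gave as many, the real one, and the highest of the others gave 14. For TE7 vs WT the real split gave 7378 and the highest other 13, again 1 of 10. For TA7 vs WT the real split gave 48 and the highest other 25, where WT replicates 1 and 2 were grouped with TA7 replicate 1. With 10 splits the share cannot fall under 0.05.

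The mean fragment length estimate of the TE7 libraries, from the effective length column that the main tests do not use, was 167.3 bases, and each TE7 library lay above each WT library. Whether the lower share of reads from transcripts of 4000 bases or more in TE7 is linked to this stays open. Within WT and TA7, the library with longer fragments had the lower share in 4 of 6 pairs, which does not decide. WT replicate 3, at 165 bases, had the highest share of the 9 libraries, at 24.79%. As a share of TPM, which is scaled per effective length, the mean was 4.31% ± 0.16 in TE7 and 5.13% ± 0.63 in WT (SD, n = 3). The change in usable positions that effective length covers is thus argued against as the whole source. A few abundant transcripts taking more of the reads is argued against, since without the 100 most abundant the TE7 minus WT difference was -4.51 percentage points, beyond the larger group SD of 2.29. A library difference of the kind that sets WT replicate 1 apart, such as RNA quality or cell state, stays open: after centring on length classes its profile correlated with TE7 minus TA7 replicates 2 and 3 at 0.392 across transcripts, between the bounds set for either outcome. An effect of the TE7 form itself also stays open, and so does a difference between the cell lines made for each construct, which no library here separates from the form.

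The large number of transcripts called in TE7 vs WT has 2 technical explanations that the tables argue against as its whole cause. With each library's length trend removed, 5972 of the 7378 calls were still made, so a length trend alone could not give them. That fit gave 995 higher and 945 lower at 4000 bases or more, against 483 and 1697 before, as its construction implies. Without WT replicate 1 and TA7 replicate 1 the count was 9895. Of the 7378 calls, 6000 were still made, so most did not need those libraries. WT replicate 1 lay nearest TE7 among the WT libraries, so a wider difference without it could be foreseen. The form of CTR1, any difference between the cell lines, and a library difference such as RNA quality or cell state remain as possible sources. None of them was tested as the source of these calls.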

How the results depend on the processing

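The fits with the length trend removed, without WT replicate 1 and TA7 replicate 1 together, and on transcripts of at least 5 CPM, and every setting of the share of long transcripts and of the side of WT on which TA7 lay, were chosen after the data were examined. Counts below are given for TA7 vs WT, TE7 vs WT, TE7 vs TA7 and the overlap of the comparisons with WT, in that order, where the main values were 48, 7378, 2411 and 44. DESeq2 gave 2206, 15850, 10555 and 1729. Without a filter the counts for TE7 vs WT and TE7 vs TA7 were 4450 and 1143. With at least 1 CPM in at least 3 libraries, TA7 vs WT gave 96, TE7 vs TA7 4311 and the overlap 93. Fits of only the 2 groups compared gave 0, 4899, 4673 and 0. With limma on log2(TPM + 1), TA7 vs WT gave 116, TE7 vs TA7 4825 and the overlap 111, and with 0.1 added these were 130, 4793 and 126. A test against a 1.5-fold change gave 16, 1003, 121 and 13, fewer by its construction. Transcripts of at least 5 CPM gave 230 for TA7 vs WT, 5476 for TE7 vs TA7 and 228 for the overlap, with fewer transcripts tested. Without WT replicate 1 and TA7 replicate 1 these were 90, 5039 and 72. Leaving out 1 library gave ranges of 5 to 159, 3129 to 9902, 298 to 4782 and 5 to 151. Except where the construction is named, the cause was not tested. RLE scaling, library size alone, the effective length offset and the removed length trend moved none of these 4 counts by over 1.5 times. With library size alone 78.9% of the TA7 vs WT calls were higher, against 66.7%.

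With a replicate block the counts were 0, 5313, 1097 and 0, with 5556 transcripts at an unadjusted p under 0.05 for TA7 vs WT in edgeR. Deviations from group means correlated at -0.034 to 0.15 between libraries of one number and at -0.146 to 0.07 between others. Of the 9, 5 correlated best with their own number in both other groups, so the numbers may pair samples. Under the replicate block ENST00000650154.1_2 in TE7 vs WT had edgeR adjusted p = 0.0525 and ENST00000630065.2_1 in TE7 vs TA7 had 0.0619, each the highest over the alternatives, of which the lowest were 1.72e-18 and 1.96e-26, both in DESeq2. ENST00000650154.1_2 in TA7 vs WT passed in DESeq2 and, with edgeR adjusted p = 0.0413, among transcripts of at least 5 CPM. In 271 other results for the 4 named transcripts the side of the threshold was as in the main values, and no change called in the main values reversed. The log2 difference of ENST00000424123.7_4 between TA7 and WT, 0.03 and not called, changed sign in several settings, to -0.33 without WT replicate 1.

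The difference in the share of long transcripts between TE7 and WT was -0.82 points as a share of TPM. Between TE7 and TA7 it was -2.38 with a limit of 6000 bases and -1.03 as a share of TPM, which weighs long transcripts less by construction. Leaving out 1 library gave -4.35 to -2.15 for TE7 vs WT, -4.3 to -3.44 for TE7 vs TA7 and -0.57 to 1.62 for TA7 vs WT, so the sign of the last rests on WT replicate 1, without which it was -0.57. The alternative that counts genes with a changed transcript, and those for gene lists, the index of long minus short genes and retained introns, were not run, because transcripts were not assigned to genes. Between 1 and 5 CPM simulated changes of 4-fold in TE7 were not recovered, while 7.97% of such transcripts were called in TE7 vs WT. Whether depth, spread or the adjustment set that limit was not tested. The percentage of TE7 vs WT calls on the same side of WT in TA7, 89.64% in the main values, was 81.66% to 93.39% with 1 library left out.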

Other observations

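The on and off transcripts and the test of their neighbours were chosen after the result was seen. In TE7 vs WT, 88 transcripts had at least 100 reads in every TE7 library and 0 in every WT library, and 89 had the reverse. In TA7 vs WT these numbers were 17 and 16, and in TE7 vs TA7 59 and 70. Of the 88 and 89, the edgeR test called 35 and 47. Reads moved between similar transcripts of one gene are a candidate explanation. Summed over the 21 rows around each of the 177 transcripts, the median absolute log2 change from WT to TE7 was 0.31. That value does not decide, because the transcripts made up a median of 9.5% of such a sum, and with no moved reads a change of 0.14 would result. For the rows around 1000 transcripts drawn at random from those of at least 5 CPM, the median was 0.24. Of the on and off transcripts that entered the edgeR test, 32.8% had a neighbour within 10 rows called in the opposite direction and 38.4% one called in the same direction. Of the 4946 called transcripts of at least 5 CPM, 20.8% and 50.3% did. These percentages go towards moved reads, but their difference was not tested, the sets were not matched on level or on the number of neighbours, and the explanation stays open. Neighbouring rows need not belong to one gene, so a table that pairs transcripts with genes would be needed to test this.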
